A study of Mus musculus with 6 samples.

How the data were processed

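Ribosome footprints of cultured Eµ-Myc; Rosa26-rtTA2 mouse lymphoma cells were measured in 6 libraries, 2 for each of the hairpins sh-Ren, sh-Eif5a and sh-Dhps, after 72 h of doxycycline at 0.9 µg/mL. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422 and aligned to the mouse build mm10 (GRCm38) with Bowtie2 and TopHat2 2.0.13. The deposited table holds raw counts of reads per RefSeq transcript, without normalization. The counting tool is not named, but the 5 closing rows of the table carry the names that htseq-count gives. Reads shared by several transcripts sit in the row of ambiguous reads (13.1 to 18.6% of reads), so genes with several transcripts lose reads. RNA-seq named in the study's design and translational efficiency were not analysed here.

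The table has 31295 transcript rows, of which 29857 identifiers matched a gene symbol and 1438 did not. Transcripts were summed per gene to 24579 features, 4058 of them genes with several transcripts. Reads on transcripts numbered 25240304 to 38322465 per library, of which 97.9 to 98.7% fell on protein-coding genes, and 8271 to 10640 genes per library had at least 10 reads. Reads outside transcripts made up 15.5 to 36.0%.

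In R 4.3.3, edgeR 4.0.16 fitted all 6 libraries in 1 quasi-likelihood model with TMM scaling and no block, after filterByExpr (minimum count 10, minimum total 15), which kept 10846 genes, 1714 of them with several transcripts. The biological coefficient of variation was 0.711, with 3 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 counted as a change. CPM are edgeR's counts scaled by the TMM-adjusted library size, and SE is the absolute log2 fold change divided by the square root of F. The comparisons were each depletion against sh-Ren, the depletions against each other, and the agreement of both depletions beside simulations of unchanged groups against the same controls. A group at 0 was set to a floor of 3 counts over the group, and genes with 1 to 3 counts in a group have a ratio with a 95% exact counting interval.

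A total of 28 gene lists with 1024 members (14 without a matching symbol) were written before the data were examined, as were the comparisons and the tests. They cover polyamine and hypusine genes, G1/S control, DNA replication, nucleotide synthesis, mitosis, ribosome biogenesis, cytosolic ribosomal proteins, translation factors, ATF4 targets, ER chaperones, p53 targets, the BCL2 family, OXPHOS, the TCA cycle, mitochondrial ribosomal proteins, mitochondrially encoded genes, autophagy and lysosome, cholesterol biosynthesis, glycolysis, interferon-stimulated genes, histones, and markers of B-lineage, pro-B and pre-B, plasma, T, myeloid, erythroid and fibroblast cells. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it.

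Named genes follow a rule fixed before the data were examined. It takes 6 genes always (Eif5a, Eif5a2, Dhps, Dohh, Odc1 and Myc), and per comparison and direction the 8 largest log2 fold changes past the threshold with a mean of at least 10 CPM and replicates that do not overlap, leaving out predicted genes, small RNA and histones. From each list it takes the up to 4 called members with the lowest adjusted p or, where fewer than 2 were called, the 2 members with the lowest p.

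Alternatives were DESeq2 1.42.0, limma voom, size factors of the median-ratio kind, library size only, scaling without the 50 most abundant genes, no filter, a filter at 10 CPM, the compared groups alone, the replicate number as a block, a rule on symbols, and each library left out in turn. Further settings chosen after the data were seen were transcripts not summed, single-transcript genes only, and leaving out genes under 1 CPM in a group. Proteins with proline tracts were not tested, because no coding sequence was at hand.

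The steps were tested on simulated data with 50 genes planted per fold. At 2-fold 8, 12 and 18% were called (sh-Eif5a against sh-Ren, sh-Dhps against sh-Ren, between the depletions), at 4-fold 66, 64 and 68%, at 8-fold 94, 90 and 98%, and at 32-fold 100, 98 and 98%. Of the 10327, 10278 and 10300 genes tested there, 18, 17 and 16 unchanged genes were called. Planted genes called at 2-, 4-, 8- and 32-fold numbered 4, 33, 47 and 50 in sh-Eif5a against sh-Ren. They numbered 6, 32, 45 and 49 in sh-Dhps against sh-Ren, and 9, 34, 49 and 49 between the depletions. In each simulation unchanged genes thus made up a larger share of the calls than the 0.05 that the threshold aims at. A planted list was called by camera in each comparison, though with an estimated correlation not between the depletions, and 0 of 20 null lists were called with either. Simulated genes were drawn independently, so members of the null lists did not vary together. In sh-Dhps against sh-Ren the estimated correlation was 0.359 for OXPHOS subunits and 0.484 for histones. The null lists therefore do not test camera's preset correlation for such lists. On shuffled fold changes, the permutation test of chromosomes in the closing part gave p under 0.05 in 2 of 100 sets without a shift. With 1 or 4 shifted chromosomes it did so in 100 of 100 sets. The permutation test of neighbours, on random sets of genes, gave p under 0.05 in 4 of 100 sets without a planted pair. With 1 planted pair it did so in 100 of 100, but 1 pair is enough for that, so this outcome was fixed in advance. The test of 1 mixture gave p under 0.05 in 10 of 100 sets simulated as 1 mixture and in 100 of 100 with ratios that differ by gene. It replaced, after the results were seen, an earlier rule that counted genes away from the median ratio against the spread between the sh-Eif5a libraries. That spread held 0 such genes, so the earlier rule could hardly fail. A first version of the check on chromosomes used 1 set and wider noise, missed its planted shift, and was replaced by the 100 sets.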

Results

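Ribosome footprints, the stretches of messenger RNA that translating ribosomes shield from nuclease, were sequenced from cultured Eµ-Myc; Rosa26-rtTA2 mouse lymphoma cells. All 6 libraries are labelled as this suspension line, which carries a Myc transgene driven in B-lineage cells. Leukocyte genes, given in the closing part, put that label in doubt for sh-Ren. Doxycycline (0.9 µg/mL for 72 h) induced a hairpin RNA against Eif5a, against Dhps or, as control, sh-Ren, named for Renilla luciferase. Each group held 2 libraries, 6 in all. The design asks how depletion of either gene acts on translation. eIF5A is a translation factor that eases peptide bonds between prolines, and Dhps encodes the enzyme that takes the first step of its hypusine modification, drawing on spermidine. Reads assigned to transcripts numbered 38322465 and 28311394 in the sh-Ren libraries, 28324723 and 27302309 in sh-Eif5a, and 25240304 and 33686242 in sh-Dhps. Across genes, which are not independent replicates, the log2 CPM (counts scaled by library size) of libraries of 1 group correlated at r = 0.901 (sh-Ren), 0.937 (sh-Eif5a) and 0.918 (sh-Dhps). Between groups r ranged from 0.753 to 0.871. The floor of 3 counts over a group lay at 0.0426 CPM in sh-Ren, 0.0561 in sh-Eif5a and 0.0518 in sh-Dhps. Such floors and all counting intervals cover counting error only. Values are means ± SD of 2 libraries unless stated. Nothing in the labels states that the libraries of a group come from separate cultures, so p-values measure the spread between samples, which can be technical.

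Both targeted genes were low in the libraries named after them. Dhps (chromosome 8, 85071486 to 85075162 on GRCm38) stood at 55.2 and 59.4 CPM in the sh-Ren libraries, 46.7 and 51.0 in sh-Eif5a and 10.3 and 8.74 in sh-Dhps. It fell by 2.59 on the log2 scale against sh-Ren (SE 0.32, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00103) and by 2.36 against sh-Eif5a (SE 0.31, same test, adjusted p = 0.00364), in 2 of 2 libraries each. Eif5a (chromosome 11, 69916712 to 69921958) has 9 transcripts in the counted annotation, and reads that several transcripts share were not assigned, so few remained. The sh-Ren libraries held 291 and 456 Eif5a reads, sh-Eif5a 0 and 14, and sh-Dhps 292 and 92. The log2 fold change in sh-Eif5a was -5.36 (SE 1.64, edgeR's quasi-likelihood test, adjusted p = 0.0634), which did not pass the threshold. With a library left out, the same test gave adjusted p = 0.00230 and 0.00344 (without sh-Ren replicate 1 or 2), 0.00529 (without sh-Eif5a replicate 2) and 0.0376 and 0.0152 (without sh-Dhps replicate 1 or 2). Without sh-Eif5a replicate 1 the log2 fold change was -4.36 and adjusted p = 0.137. Dohh, which completes hypusine formation, stood at 56.1 ± 2.74 CPM in sh-Ren, 59.1 ± 30.5 in sh-Eif5a and 75.8 ± 12.5 in sh-Dhps. Odc1, the enzyme that opens polyamine synthesis and a known MYC target, stood at 359 ± 0.922, 536 ± 0.910 and 569 ± 98.8 CPM, and did not pass with all libraries (adjusted p = 0.152, 0.152 and 0.920 by edgeR's quasi-likelihood test). Odc1 passed in sh-Eif5a against sh-Ren without sh-Dhps replicate 1 or 2 (adjusted p = 0.0127 and 0.0120) or with these groups alone (0.0248), in sh-Dhps against sh-Ren without sh-Dhps replicate 1 (0.00997), and in both with DESeq2 (0.0453 and 0.0431). The second isoform gene, Eif5a2, had no read in sh-Ren and 2.33 ± 2.33 and 2.42 ± 0.983 CPM in the depleted groups. Eif5a2 did not pass edgeR's test, but was called by DESeq2 in both (adjusted p = 0.00110 and 0.00188) and, without a filter on low counts, by edgeR in sh-Eif5a (0.0494). Myc itself, with 4 transcripts in the annotation, had 0 assigned reads in all 6 libraries and cannot be assessed.

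**Figure D1:**
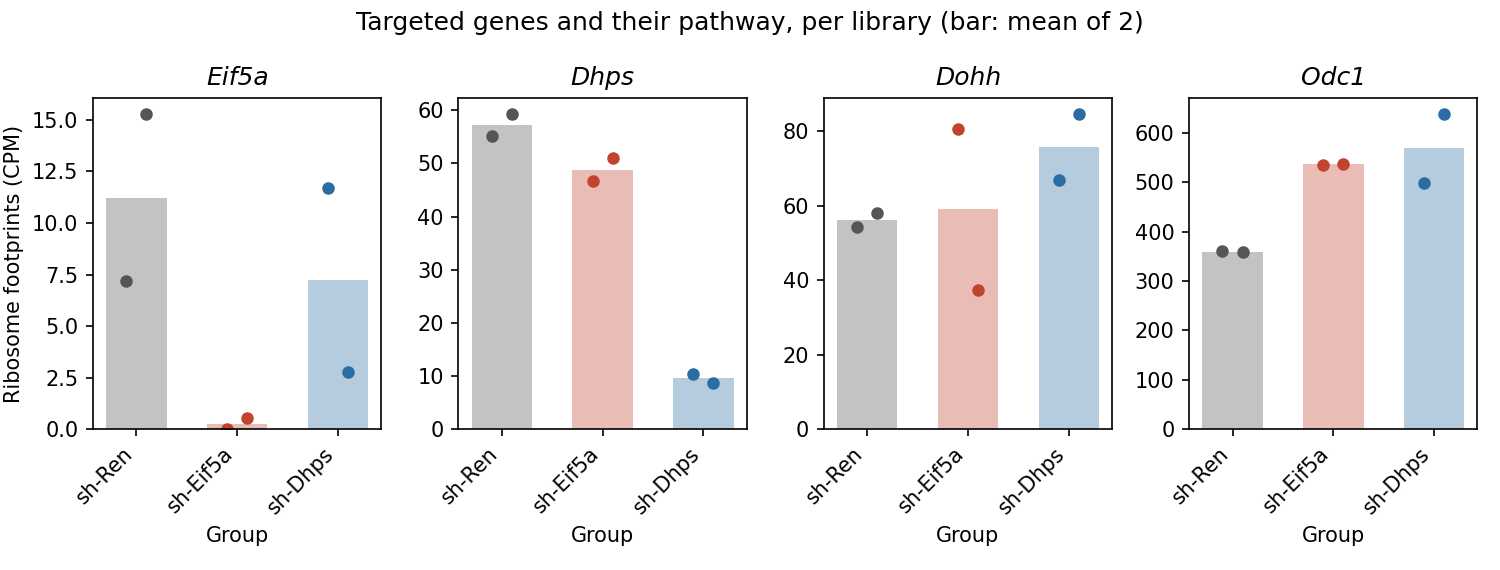
Ribosome footprints in CPM (vertical axes, linear from 0) of Eif5a, Dhps, Dohh and Odc1 in the 3 groups. Points are libraries and bars are means of 2; Dhps stands at 10.3 and 8.74 CPM in the sh-Dhps libraries, below all others, and Eif5a at 0 and 0.541 CPM in the sh-Eif5a libraries.

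Depletion of Eif5a against sh-Ren: Most B-lineage genes listed were abundant in the sh-Eif5a libraries and almost without reads in sh-Ren. The sh-Ren cells may thus be of another kind, so no difference from sh-Ren, in either depletion, can be assigned to the depletion alone. Cd79a and Cd79b, the signalling chains of the B cell receptor, stood at 741 ± 3.20 and 320 ± 24.0 CPM against 0.225 ± 0.109 and 0.0952 ± 0.0397. Igll1 and Vpreb1, which form the surrogate light chain of pre-B cells, stood at 669 ± 53.1 and 319 ± 0.342 CPM against 0.22 ± 0.0678 and 0.0750 ± 0.0363. Pax5, the transcription factor that holds B cell identity, had no read in sh-Ren and was at least 3124-fold higher in sh-Eif5a (133 ± 3.48 CPM). Rag2, part of the recombinase that joins receptor gene segments, was at least 3157-fold higher, and the receptor adaptor Blnk at least 2583-fold. Hcls1, Septin1, Robo2, the activation antigen Cd69 and Rab7b, likewise without reads in sh-Ren, were at least 2861-, 2442-, 1925-, 1557- and 1467-fold higher. Of 15 tested B-lineage markers 14 rose (15 adjusted over the list alone), with a median log2 fold change of 10.98, or 10.70 with the genes at 0 set to their bound. The list test, camera with a preset correlation, gave adjusted p = 7.11e-63, and adjusted p = 0.00942 with an estimated correlation. Of 12 markers of pro-B and pre-B cells 9 rose (10 adjusted over the list alone), with a median of 11.11, or 10.82 with bounds (camera, adjusted p = 1.52e-39; adjusted p = 0.010 with an estimated correlation). Of the latter Sox4, Bach2 and Erg were not near 0 in sh-Ren (78.5, 2.27 and 1.76 CPM).

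Markers of other cell types moved in both directions. Of 8 plasma cell markers, Mzb1 and Irf4 rose (162 ± 5.30 and 45.7 ± 13 CPM against 0.0291 and 0.0336) and Cd38 fell (2.43 ± 1.42 against 43.8 ± 6.27 CPM), and 3 rose and 1 fell adjusted over the list alone. The plasma cell list passed camera (adjusted p = 0.0122; adjusted p = 0.729 with an estimated correlation), but not with any of the 6 libraries left out (adjusted p from 0.0813 to 0.432), with limma voom (0.355), with the replicate block (0.203) or without a filter on low counts (0.0953). Among 5 T cell markers Cd28, a costimulatory receptor, rose to 17.6 ± 0.855 CPM from no read (at least 413-fold), and 3 rose adjusted over the list alone; the list did not pass (camera, adjusted p = 0.120), but did without sh-Ren replicate 2 (0.0122), sh-Eif5a replicate 1 (0.0188) or 2 (0.0410), or sh-Dhps replicate 1 (0.0187) or 2 (0.0180). The 5 myeloid markers held no call by edgeR (3 had an unadjusted p under 0.05, 3 were called by DESeq2 and 0 by limma voom), but edgeR called Mrc1 without sh-Ren replicate 1 (adjusted p = 0.00819). Of 13 erythroid markers listed, 12 were in the table and 2 had enough reads for a test, with at most 2.75 CPM in any library. Fibroblast markers fell as a list (median -4.06, camera, adjusted p = 0.00776, and 0.729 with an estimated correlation). Of 20 listed only 8 had enough reads for a test, 6 with a negative and 2 with a positive log2 fold change. Of these 8, 4 fell, 4 also adjusted over the list alone. Among them was Lum, a proteoglycan of connective tissue, at 1.39 ± 1.04 against 96.5 ± 9.10 CPM. Tested markers of the other lists numbered 15 of 23 (B-lineage), 12 of 14 (pro-B and pre-B), 8 of 10 (plasma cell), 5 of 15 (T cell) and 5 of 16 (myeloid). A gene can enter the test through reads in 1 group alone.

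Among genes that fell in sh-Eif5a, beside B-lineage markers near 0 in sh-Ren, was Cdkn1a. Cdkn1a, the p53-induced cyclin-dependent kinase inhibitor p21, stood at 0.310 ± 0.330 CPM against 39.9 ± 13.1 in sh-Ren. The thrombin receptor gene F2r was 339-fold lower and Nlgn2 250-fold lower, and Hr, without reads in sh-Eif5a, was at least 616-fold lower. Ptpn14, with 2 reads left, had a ratio of 0.000471 (95% exact counting interval 5.70e-05 to 0.00170). Ddit4l, with a ratio of 0.000734 (1.86e-05 to 0.00410), and Vasn, with 0.00185 (0.000381 to 0.00541), fell as well. Kctd12b was at least 453-fold lower, although limma voom did not call it (adjusted p = 0.0759). Cdkn2a (chromosome 4, 89274473 to 89294619), which encodes the inhibitors p16Ink4a and p19Arf, went the other way: 139 ± 25.7 CPM against 2 reads in sh-Ren, a ratio of 4918 (1361 to 40613). The cyclin D partner Cdk6 also rose (186 ± 3.19 against 50.9 ± 2.70 CPM). Of the 32 tested genes of G1/S control 6 rose and 5 fell (7 and 6 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.851).

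Cholesterol biosynthesis and glycolysis fell as lists in the same comparison in which B-lineage markers averaged 187 CPM in sh-Eif5a and 0.0925 CPM in sh-Ren. Such falls cannot be told apart from a difference in the kind of cells. Of 23 genes of cholesterol biosynthesis and its control 9 fell (13 adjusted over the list alone). They included Pcsk9, which degrades the LDL receptor (2.08 ± 0.593 against 35.8 ± 4.29 CPM), the sterol sensor partner Insig1 (21.9 ± 3.10 against 179 ± 25), Hmgcr, the rate-limiting enzyme (194 ± 12.8 against 643 ± 160), and the synthase Lss (27.5 ± 7.58 against 101 ± 7.03). The list median was -0.99 (camera, adjusted p = 2.50e-06; adjusted p = 0.729 with an estimated correlation). Of 19 glycolysis genes 6 fell (11 adjusted over the list alone; median -0.90, camera, adjusted p = 0.00339; adjusted p = 0.783 with an estimated correlation), among them Pfkp, a phosphofructokinase, at 208 ± 1.49 against 1016 ± 302 CPM, and the glucose transporter Slc2a1 at 84.5 ± 19.4 against 361 ± 188. Of 42 targets of ATF4, the transcription factor of the integrated stress response, 8 fell and 1 rose, as adjusted over the list alone. Psat1 of serine synthesis (39.0 ± 13.7 against 192 ± 7.36 CPM), Pck2 (58.9 ± 28.5 against 239 ± 47.5) and Aldh1l2 (7.56 ± 1.90 against 41.3 ± 6.99) were among those that fell. The ATF4 list passed camera (median -0.44, adjusted p = 0.0277; adjusted p = 0.982 with an estimated correlation), but not without sh-Ren replicate 1 (adjusted p = 0.196) or sh-Eif5a replicate 2 (adjusted p = 0.0572), nor with single-transcript genes only (adjusted p = 0.0951).

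Genes of ribosome assembly and of mitochondrial translation held single members that rose, in lists that did not pass, again beside B-lineage markers near 0 in sh-Ren. Nop10, a protein of H/ACA guide particles (867 ± 181 against 192 ± 6.73 CPM), the nucleolar chaperone Npm1 (79.9 ± 5.41 against 19.7 ± 2.31), Rcl1 (394 ± 31.9 against 142 ± 2.05) and Utp14a (195 ± 8.23 against 58.8 ± 4.73) were among 6 of 71 ribosome biogenesis genes that rose, 6 also adjusted over the list alone (list by camera, adjusted p = 0.126). Mrpl35 (293 ± 9.36 against 108 ± 3.79) and Mrpl50 (233 ± 2.25 against 93.4 ± 0.566) were among 8 of 78 mitochondrial ribosomal proteins that rose, 8 also adjusted over the list alone (list, adjusted p = 0.143). Of 56 replication-dependent histone genes 6 rose and 1 fell, as adjusted over the list alone, with H2bc15 at 77.8 ± 8.30 against 19.9 ± 0.441 CPM and H2bc4 at 213 ± 6.24 against 66.3 ± 18.1 (list, adjusted p = 0.238). Histone genes have near-identical copies, so their single values are uncertain. Sqstm1, the autophagy receptor p62, fell (95.4 ± 4.48 against 306 ± 9.56), as did the lysosomal protease Ctsa (5.89 ± 2.53 against 31.3 ± 9.35), within 44 autophagy and lysosome genes of which 2 fell and 2 rose (list, adjusted p = 0.975). Of 32 p53 targets 5 fell, 5 also adjusted over the list alone, Cdkn1a and Ddit4l among them (list, adjusted p = 0.143). Mtap, which salvages the by-product of polyamine synthesis and lies beside Cdkn2a (chromosome 4, 89137370 to 89181090), fell to 322 ± 14.7 from 883 ± 142 CPM, within 15 polyamine and hypusine genes (list, adjusted p = 0.975). The lists of DNA replication (adjusted p = 0.617), nucleotide synthesis (0.276), mitosis (0.120), cytosolic ribosomal proteins (0.436), translation factors (0.445), ER chaperones (0.975), the BCL2 family (0.975), OXPHOS subunits (0.856), the TCA cycle (0.445), interferon-stimulated genes (0.406) and myeloid markers (0.617) did not pass camera either. Several of these lists passed camera with 1 library left out. Without sh-Ren replicate 2 adjusted p was 0.000576 for ribosome biogenesis, 0.000532 for mitochondrial ribosomal proteins, 0.00435 for both cytosolic ribosomal proteins and histones, 0.0173 for nucleotide synthesis, 0.0209 for translation factors and 0.0440 for interferon-stimulated genes. Without sh-Eif5a replicate 2 it was 0.0410 for ribosome biogenesis and for mitochondrial ribosomal proteins, 0.0455 for histones and 0.0483 for mitosis. Without sh-Dhps replicate 1 or 2 it was 0.000610 and 0.000714 for ribosome biogenesis, 0.00775 and 0.00837 for mitochondrial ribosomal proteins and for mitosis, 0.00775 and 0.00993 for cytosolic ribosomal proteins, 0.0196 and 0.0180 for histones, and 0.0187 and 0.0180 for nucleotide synthesis.

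In all, 1352 of 10846 tested genes changed, 729 higher and 623 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg), and 2838 had an unadjusted p under 0.05. Of the genes that rose, 121 had no read in sh-Ren. DESeq2 called 2241 genes. More genes were lower than higher with library size as the only scaling (598 higher and 717 lower, with the median log2 fold change of all genes at -0.08 in place of 0.04), with a filter at 10 CPM (591 and 634), without sh-Ren replicate 2 (685 and 818) and without genes under 1 CPM in a group (392 and 513). The count was 2274 or 2316 without sh-Dhps replicate 1 or 2, 2085 without sh-Ren replicate 1 and 857 without sh-Eif5a replicate 2.

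Depletion of Dhps against sh-Ren: Most B-lineage genes listed were abundant in sh-Dhps and, but for the same 3, almost without reads in sh-Ren. Cd79a stood at 408 ± 166 CPM, Cd79b at 171 ± 40.8 and Igll1 at 359 ± 59.5, against 0.225, 0.0952 and 0.22 CPM in sh-Ren. Blnk, Cd69, Septin1, Pax5 and Hcls1, without reads in sh-Ren, were at least 1206-, 1008-, 970-, 853- and 727-fold higher. The lymphocyte adaptor Sash3, the adhesion molecule Icam2 and the transporter Slc15a3 were at least 1198-, 604- and 494-fold higher. Of 15 B-lineage markers 13 rose (15 adjusted over the list alone), with a median of 10.46, or 9.48 with bounds (camera, adjusted p = 1.62e-79; adjusted p = 0.00659 with an estimated correlation). Of 12 pro-B and pre-B markers 8 rose (10 adjusted over the list alone), with a median of 9.84, or 7.93 with bounds (camera, adjusted p = 3.07e-42; adjusted p = 0.00904 with an estimated correlation). Mzb1 (93.8 ± 22.7 CPM against 0.0291) and Irf4 (20.5 ± 11.1 against 0.0336) rose among 8 plasma cell markers, and 3 rose and 1 fell adjusted over the list alone. That list passed camera (adjusted p = 0.000427; adjusted p = 0.567 with an estimated correlation), but not without sh-Ren replicate 1 (0.115) or 2 (0.0803), sh-Eif5a replicate 1 (0.104) or 2 (0.0838), or sh-Dhps replicate 1 (0.148), nor with limma voom (0.325) or the replicate block (0.0766). Limma voom did not call Irf4 either (adjusted p = 0.0623). Of 5 T cell markers 2 rose, Lck and Cd28 (3 adjusted over the list alone), but neither without sh-Dhps replicate 1 (edgeR's quasi-likelihood test, adjusted p = 0.147 and 0.0724) or with limma voom (adjusted p = 0.0551 and 0.218). Lck was also not called with the compared groups alone (0.0773) or the replicate block (0.0529). The T cell list did not pass (camera, adjusted p = 0.0535), but did without sh-Ren replicate 2 (0.00370), sh-Eif5a replicate 1 (0.00139) or 2 (0.00180), or sh-Dhps replicate 1 (0.0142) or 2 (0.00720).

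The largest falls in sh-Dhps, beside B-lineage markers near 0 in sh-Ren, included Nid2. Nid2, a basement membrane nidogen, stood at 14.9 ± 4.44 against 850 ± 93.4 CPM in sh-Ren, and Lum at 3.40 ± 0.854 against 96.5 ± 9.10. Aebp1, which binds collagen, was 102-fold lower, Dock6 73.3-fold, the phosphatase gene Ptpn14 59.0-fold, Selenbp1 52.2-fold, Wdr90 50.2-fold and Prune2 39.9-fold. Kctd12b was 70.7-fold lower, but not past the test without sh-Ren replicate 1 (edgeR's quasi-likelihood test, adjusted p = 0.161) or with limma voom (adjusted p = 0.168). The fibroblast list fell (2 of 8 members, 3 adjusted over the list alone; median -1.29, or -2.23 with bounds; camera, adjusted p = 0.0142; adjusted p = 0.641 with an estimated correlation), but not without sh-Ren replicate 1 (0.0981) or sh-Dhps replicate 2 (0.0994). Of the 8 fibroblast markers tested, from 20 listed, 5 had a negative and 3 a positive log2 fold change. Cdkn2a rose, at 47.2 ± 18.2 CPM against 2 reads in sh-Ren, a ratio of 1598 (442 to 13203). Perp, a p53-induced membrane protein of desmosomes, rose to 148 ± 65.9 from 23.1 ± 2.25 CPM, among 32 p53 targets (list by camera, adjusted p = 0.796). Lamp1, a lysosomal membrane glycoprotein, rose to 1342 ± 277 from 472 ± 25.2 CPM, among 44 autophagy and lysosome genes. That list did not pass (camera, adjusted p = 0.104), but did without sh-Ren replicate 2 (0.0296), sh-Eif5a replicate 1 (0.0201) or 2 (0.0239), or sh-Dhps replicate 2 (0.0107).

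Energy metabolism moved in both directions, beside B-lineage markers that averaged 91.0 CPM in sh-Dhps and 0.0925 in sh-Ren. Of 19 glycolysis genes 5 fell (11 adjusted over the list alone; median -1.10, camera, adjusted p = 1.00e-06; adjusted p = 0.567 with an estimated correlation). Pgk1, phosphoglycerate kinase, stood at 1539 ± 269 against 4442 ± 1122 CPM, Tpi1 at 905 ± 26.4 against 2262 ± 616 and Pfkl at 107 ± 65.5 against 509 ± 118. Of 72 nuclear-encoded OXPHOS subunits 4 rose (24 adjusted over the list alone; median 0.60, camera, adjusted p = 0.000221; adjusted p = 0.883 with an estimated correlation; 0.110 without sh-Ren replicate 1), such as Cox6a1 of cytochrome c oxidase at 490 ± 171 against 129 ± 20.4 CPM. Of 78 mitochondrial ribosomal proteins 3 rose, 3 also adjusted over the list alone (median 0.55, camera, adjusted p = 0.000221; adjusted p = 0.641 with an estimated correlation; 0.0608 without sh-Ren replicate 1). Mrps6 stood at 153 ± 19.2 against 56.8 ± 1.44 CPM. With the compared groups fitted alone, neither Mrps6 nor the other called members, Mrpl2 and Mrps18a, passed (edgeR's quasi-likelihood test, adjusted p = 0.0540, 0.102 and 0.112). Mrpl2 also missed the threshold without sh-Ren replicate 1 or 2 (0.104 and 0.0643), and Mrps18a without sh-Ren replicate 1 (0.141) or with library size as the only scaling (0.0527). Without genes under 1 CPM in a group Mrpl2 and Mrps18a did not pass (0.0522 and 0.0721). Cholesterol biosynthesis fell (4 of 23 members; 5 lower and 1 higher adjusted over the list alone; median -0.39, camera, adjusted p = 0.0283; adjusted p = 0.844 with an estimated correlation), but not without sh-Ren replicate 2 (adjusted p = 0.562), with a filter at 10 CPM (0.101) or without genes under 1 CPM in a group (0.0525). Leaving out sh-Ren replicate 2 also ended the calls of its 4 members Sqle, Hmgcr, Stard4 and Insig1 (edgeR's quasi-likelihood test, adjusted p = 0.22, 0.256, 0.159 and 0.101). Without sh-Eif5a replicate 1 adjusted p was 0.0599 for Sqle, 0.0543 for Hmgcr and 0.0560 for Stard4, without sh-Eif5a replicate 2 it was 0.0503 for Sqle, and without sh-Dhps replicate 2 it was 0.0524 for Stard4. With the compared groups alone (0.104, 0.112, 0.0836 and 0.0967) or without genes under 1 CPM (0.0557, 0.0649, 0.0511 and 0.0649) none of the 4 passed, and Insig1 also missed the threshold when scaled without the 50 most abundant genes (0.0507) or with transcripts not summed (0.0503).

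Lists of growth and division are given beside the same B-lineage markers near 0 in sh-Ren. Mitosis genes fell as a list (median -0.50 over 41 genes, camera, adjusted p = 0.000934; adjusted p = 0.708 with an estimated correlation). No single member was called by edgeR, 8 had an unadjusted p under 0.05, DESeq2 called 2 and limma voom 3. With a library left out edgeR called 1 and 3 members (without sh-Ren replicate 1 or 2), 1 and 2 (without sh-Eif5a replicate 1 or 2), and 3 and 17 (without sh-Dhps replicate 1 or 2). Kif23, a kinesin, was called in each of these 6 fits, and without a filter on low counts 7 members were called. Cenpf, a kinetochore protein, had 187 ± 46.6 against 388 ± 43.0 CPM, and passed without sh-Dhps replicate 1 or 2 (adjusted p = 0.0297 and 0.000409). Cytosolic ribosomal proteins rose as a list (3 of 78 members, 2 adjusted over the list alone; median 0.37, camera, adjusted p = 0.0281; adjusted p = 0.899 with an estimated correlation), but not without sh-Ren replicate 1 (0.605), scaled by library size only (0.0623) or under the rule on symbols (0.0650). Histone genes rose as a list (5 of 56 members, 8 adjusted over the list alone; median 0.52, camera, adjusted p = 0.0281; adjusted p = 0.899 with an estimated correlation), but not without sh-Ren replicate 1 (0.605) or sh-Dhps replicate 1 (0.744), or scaled by library size only (0.0522). H2bc15 stood at 179 ± 29.3 against 19.9 ± 0.441 CPM and H2bc4 at 331 ± 102 against 66.3 ± 18.1. Dut, which clears dUTP, rose to 80.8 ± 28.6 from 16.8 ± 2.24 CPM, and Nop10 to 657 ± 251 from 192 ± 6.73. Their lists, nucleotide synthesis and ribosome biogenesis, did not pass (camera, adjusted p = 0.983 and 0.815), but rose without sh-Dhps replicate 1 (medians 0.29 and 0.33, adjusted p = 0.0105 and 5.90e-05) and fell without sh-Dhps replicate 2 (medians -0.28 and -0.32, adjusted p = 0.00774 and 8.88e-05). Camera did not call polyamine and hypusine genes (adjusted p = 0.802), G1/S control (0.699), DNA replication (0.0892), translation factors (0.829), ATF4 targets (0.104), ER chaperones (0.291), the BCL2 family (0.657), the TCA cycle (0.657), interferon-stimulated genes (0.934) or myeloid markers (0.934). With 1 library left out camera called DNA replication (0.0159 without sh-Ren replicate 1, 2.91e-06 without sh-Dhps replicate 2), translation factors (0.00544 without sh-Dhps replicate 1) and ATF4 targets (0.0296 without sh-Ren replicate 2, 0.0374 without sh-Dhps replicate 2). It also called ER chaperones (0.0477 and 0.0478 without sh-Eif5a replicate 1 or 2, 0.00290 without sh-Dhps replicate 2).

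In this comparison 623 of 10846 genes changed, 418 higher and 205 lower, and 2029 had an unadjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The count was 1808 without sh-Dhps replicate 2, 1331 without sh-Ren replicate 1, 345 with the compared groups fitted alone, 1332 with DESeq2 and 1235 without a filter on low counts. Without the genes under 1 CPM in a group, a setting chosen after the data were seen, 242 genes passed, of which 112 were higher and 130 lower.

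**Figure D2:**
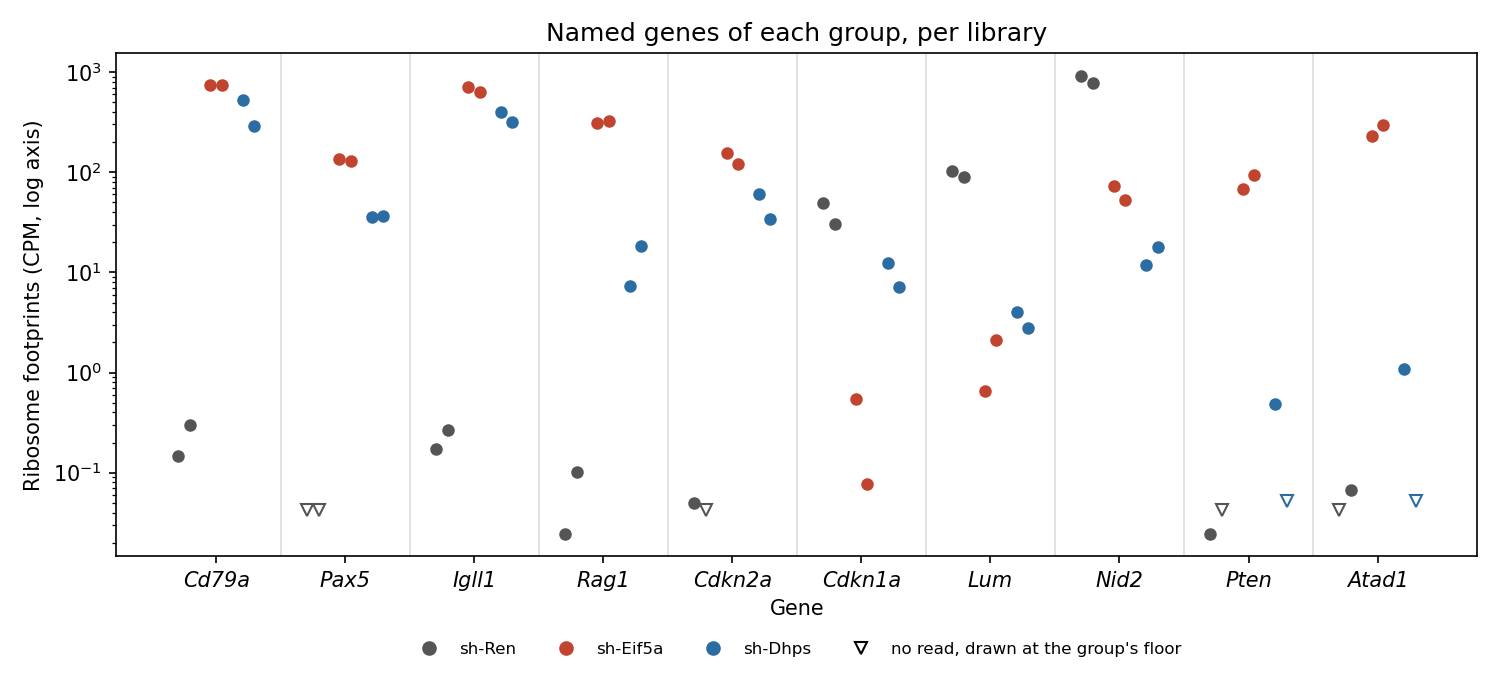
Ribosome footprints in CPM (vertical axis, logarithmic) of 10 named genes, 1 point per library. Open triangles mark libraries without a read, drawn at the group's floor of 3 counts; Cd79a, Pax5, Igll1, Rag1 and Cdkn2a lie near the floor in sh-Ren, and Pten and Atad1 near it in sh-Ren and sh-Dhps.

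The depletions compared with each other: genes of early B cell development were lower in sh-Dhps than in sh-Eif5a. So were 17 genes of leukocytes in general, with medians of 62.6 against 160 CPM and a median ratio of 0.415. These are the genes of a list of 25 with at least 20 CPM in sh-Eif5a, a check chosen after the result was seen. A cutoff on sh-Eif5a can lower this ratio, and the marker lists below have no such cutoff, so the sizes cannot be ranked. Whether B-lineage genes fell more than leukocyte genes in general was not tested, though single genes fell further than this ratio. Rag1 and Rag2, the receptor recombinase, stood at 12.7 ± 7.74 and 12.3 ± 7.04 CPM against 317 ± 8.29 and 135 ± 17.4. Vpreb1 stood at 69.7 ± 18.7 against 319 ± 0.342 CPM and Il7r, the interleukin 7 receptor of early B cells, at 54.4 ± 12.9 against 260 ± 28.8. These were the 4 pro-B and pre-B markers of 12 that fell, with 6 adjusted over the list alone (median -1.16, camera, adjusted p = 5.35e-09; adjusted p = 0.187 with an estimated correlation). Pax5 (36.4 ± 0.394 against 133 ± 3.48 CPM) and Ebf1, another transcription factor of the lineage (44.5 ± 7.67 against 163 ± 20.6), were the 2 of 15 B-lineage markers that fell, with 9 lower and 1 higher adjusted over the list alone (median -1.10, camera, adjusted p = 2.11e-05; adjusted p = 0.187 with an estimated correlation).

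Some genes were present in 1 depleted group and close to 0 in the other. Pten, the phosphatase that opposes PI3-kinase signalling (chromosome 19, 32757577 to 32826160), stood at 67.5 and 93.0 CPM in the sh-Eif5a libraries, 0.480 and 0 in sh-Dhps and 0.0246 and 0 in sh-Ren. Its neighbour Atad1 (chromosome 19, 32672558 to 32739787), a mitochondrial membrane ATPase, stood at 232 and 294 CPM in sh-Eif5a, 1.08 and 0 in sh-Dhps and 0 and 0.0671 in sh-Ren. Prss12 (0.560 ± 0.792 against 124 ± 13.6 CPM), Rab7b (0.160 ± 0.226 against 62.5 ± 2.45) and Sash1 (0.10 ± 0.141 against 35.8 ± 2.40) were also lower in sh-Dhps. Arl5c and the costimulatory receptor Icos had ratios of 0.000616 (1.56e-05 to 0.00344) and 0.00116 (0.000140 to 0.00420), although limma voom did not call Icos (adjusted p = 0.0531). Tmlhe was 149-fold lower, but not past the test without sh-Eif5a replicate 2 (edgeR's quasi-likelihood test, adjusted p = 0.212) or with limma voom (adjusted p = 0.0864). On the other side, Perp stood at 148 ± 65.9 against 2.29 ± 1.24 CPM and Gpx8, an oxidoreductase of the endoplasmic reticulum, at 43.2 ± 7.12 against 0.762 ± 0.203. Lpar2 (62.1-fold), Tuba8 (97.1-fold), the B cell kinase Blk (73.9-fold), Ostn (301-fold), Ptgfrn (841-fold, interval 232 to 6950) and Flnc (2899-fold, interval 520 to 114535) were higher too, but none of these 6 was called by limma voom (adjusted p = 0.0929, 0.101, 0.0626, 0.0596, 0.0611 and 0.253).

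Cholesterol biosynthesis and OXPHOS subunits rose as lists in sh-Dhps against sh-Eif5a, beside B-lineage and pro-B and pre-B markers with medians of -1.10 and -1.16. Pcsk9 stood at 73.0 ± 1.89 against 2.08 ± 0.593 CPM. It and Insig1 (75.9 ± 25.2 against 21.9 ± 3.10) were the 2 of 23 genes of cholesterol biosynthesis that rose, 2 also adjusted over the list alone (median 0.63, camera, adjusted p = 2.30e-05; adjusted p = 0.785 with an estimated correlation). The call of Insig1 was lost without sh-Eif5a replicate 2 (edgeR's quasi-likelihood test, adjusted p = 0.0635). OXPHOS subunits rose as a list (3 of 72 members, 3 adjusted over the list alone; median 0.41, camera, adjusted p = 2.82e-05; adjusted p = 0.847 with an estimated correlation). Ctsa (50.7 ± 0.499 against 5.89 ± 2.53 CPM) and Sqstm1 (357 ± 107 against 95.4 ± 4.48) were among 3 of 44 autophagy and lysosome genes that rose, 5 adjusted over the list alone (list, adjusted p = 0.0536). Of 32 p53 targets 4 rose, with 4 higher and 1 lower adjusted over the list alone (list, adjusted p = 0.0719). They included Perp and, at 9.79 ± 3.8 against 0.310 ± 0.330 CPM, Cdkn1a, which limma voom did not call (adjusted p = 0.187). Rpl19, a ribosomal protein gene with several transcripts, rose to 686 ± 102 from 146 ± 11.2 CPM, the 1 call among 78 cytosolic ribosomal proteins, 1 also adjusted over the list alone (list, adjusted p = 0.209). Col5a1, a fibrillar collagen, stood at 23.7 ± 2.01 against 0.913 ± 0.143 CPM among 8 fibroblast markers (list, adjusted p = 0.286), without a call by limma voom (adjusted p = 0.151).

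Beside the same fall of B-lineage markers (median -1.10), genes of DNA replication and ribosome biogenesis fell as lists by medians of -0.27 and -0.31 (camera, adjusted p = 0.00315 and 0.00331; adjusted p = 0.847 for both with an estimated correlation), but neither passed without sh-Dhps replicate 1 (adjusted p = 0.691 and 0.883). In that library 36.0% of reads lay outside transcripts, against 21.3% in the other sh-Dhps library, and snoRNA held 0.102% of transcript reads against 0.181%. No DNA replication gene was called by edgeR among 59 (7 had an unadjusted p under 0.05, DESeq2 called 2 and limma voom 1). With a library left out edgeR called 1 and 2 members (without sh-Ren replicate 1 or 2), 1 (without sh-Dhps replicate 1) and 19 (without sh-Dhps replicate 2), and 4 without a filter on low counts. Prim1, a primase subunit, had 121 ± 3.58 against 248 ± 33.2 CPM and was among those called in each of these 4 fits with a library left out (adjusted p = 0.0494, 0.0372, 0.0147 and 0.00882). Npm1, the 1 ribosome biogenesis gene of 71 past the test, stood at 28.1 ± 6.78 against 79.9 ± 5.41 CPM, but not past it without sh-Eif5a replicate 1 (edgeR's quasi-likelihood test, adjusted p = 0.107), sh-Eif5a replicate 2 (0.185) or sh-Dhps replicate 1 (0.0608). Camera did not call mitochondrial ribosomal proteins (adjusted p = 0.0616), nucleotide synthesis (0.0932), ATF4 targets (0.152), interferon-stimulated genes (0.190), ER chaperones (0.209), mitosis (0.265), glycolysis (0.308), myeloid markers (0.314), translation factors (0.371), histones (0.433), the BCL2 family (0.433), the TCA cycle (0.649), polyamine and hypusine genes (0.804), T cell markers (0.804), plasma cell markers (0.983) or G1/S control (0.983). Without sh-Dhps replicate 2 it called mitochondrial ribosomal proteins (0.000502), nucleotide synthesis (1.63e-06), mitosis (0.000138), cytosolic ribosomal proteins (2.58e-05), translation factors (0.00594), ER chaperones (0.000513), glycolysis (0.0352), histones (0.000414) and the autophagy and lysosome list (0.0108). Without sh-Eif5a replicate 1 it called ATF4 targets (0.00834), p53 targets (0.0410), autophagy and lysosome (0.0406), nucleotide synthesis (0.0488) and mitochondrial ribosomal proteins (0.0406), and without sh-Dhps replicate 1 the TCA cycle (0.0473). Mitochondrial ribosomal proteins passed also without sh-Ren replicate 1 (0.0424) or 2 (0.0107) or sh-Eif5a replicate 2 (0.0371).

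Between the depletions 367 of 10846 genes differed, 242 higher and 125 lower in sh-Dhps, and 1720 had an unadjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The balance turned with limma voom (126 higher and 154 lower) and without sh-Dhps replicate 2 (584 and 775). Fitted without the sh-Ren libraries, 536 genes passed, and 341 of them were among the 367. The count was 769 and 1086 without sh-Ren replicate 1 or 2, 556 and 1359 without sh-Dhps replicate 1 or 2, 977 with DESeq2 and 859 without a filter on low counts.

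**Figure D3:**
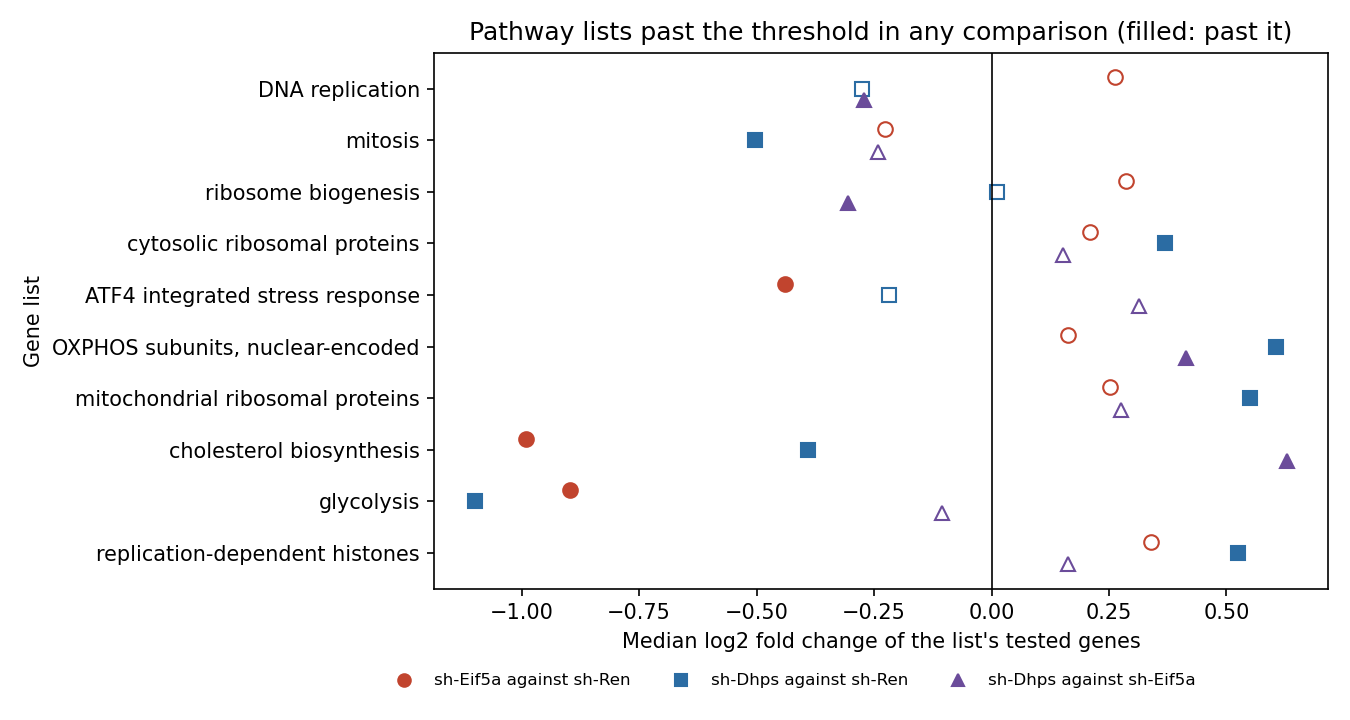
Median log2 fold change (horizontal axis) of the tested genes of each pathway list that passed camera in any comparison, with 1 symbol per comparison. Filled symbols passed; cholesterol biosynthesis lies at -0.99 and -0.39 against sh-Ren and at 0.63 between the depletions, and none of the filled symbols shown stays past the threshold with an estimated correlation.

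Some lists without a call had a median, a mean and a test that differed in sign. Against sh-Ren this held in sh-Eif5a for polyamine and hypusine genes, G1/S control, the BCL2 family and autophagy and lysosome genes. In sh-Dhps it held for polyamine and hypusine genes, G1/S control, nucleotide synthesis, ribosome biogenesis, p53 targets and the TCA cycle. Between the depletions it held for polyamine and hypusine genes, mitosis, T cell markers and fibroblast markers. The mitochondrially encoded genes had 0 members in the table.

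Both depletions share the sh-Ren libraries, so their fold changes correlate without any effect. Across 10846 genes the log2 fold changes of the depletions correlated at r = 0.711 with a covariance of 5.28, where 20 simulations of unchanged groups against the same controls averaged r = 0.494 and a covariance of 1.01. The difference of the covariances was 4.27. Both depletions called 343 genes higher and 129 lower, where the simulations averaged 0.15 and 0 (at most 1 and 0), and 4 genes were called in opposite directions. Among the 8796 genes with at least 1 CPM in sh-Ren, r was 0.560, with a covariance of 1.47 and 123 shared higher and 129 shared lower calls. The same selection in the simulations averaged r = 0.425 and a covariance of 0.447, with the same 0.15 and 0 shared calls. The shared higher calls hold the B-lineage genes without reads in sh-Ren, such as Pax5, Blnk, Cd69, Septin1 and Hcls1. The simulations gave all groups 1 mean per gene, so they hold no controls of another kind of cell. If the sh-Ren cells are of another kind, both depletions share calls in both directions without a common effect. The excess over the simulations therefore cannot show that the depletions agree. Since 2 control libraries cannot be split into groups of 2, the part that comes from the shared controls is unknown. The shared count of 472 became 1079 without sh-Ren replicate 1, 1014 without sh-Dhps replicate 2, 935 with DESeq2, 852 without a filter on low counts and 172 without genes under 1 CPM in a group.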

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

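The comparison between the depletions was chosen before the data were examined, and the tests of explanations in this part were chosen only after the result was seen. Both depletions have sh-Ren as control. The depleted groups may also hold different cells, since 17 leukocyte genes, described below, had a median ratio of sh-Dhps over sh-Eif5a of 0.415. These genes were kept by their level in sh-Eif5a, which can lower the ratio. The direct test between the depletions found 367 genes that differ, which the design cannot assign to the hairpins alone. List medians of that difference were -0.27 for DNA replication, -0.31 for ribosome biogenesis, 0.41 for OXPHOS subunits, 0.63 for cholesterol biosynthesis, -1.10 for B-lineage markers and -1.16 for pro-B and pre-B markers. With an estimated correlation none of the 6 lists passed (camera, adjusted p = 0.847 for the first 3, 0.785 for cholesterol biosynthesis and 0.187 for both marker lists). The DNA replication and ribosome biogenesis lists also lost their call without sh-Dhps replicate 1 (camera, adjusted p = 0.691 and 0.883). Among genes named against sh-Ren, the log2 difference (sh-Dhps minus sh-Eif5a) was -2.36 for Dhps, -3.45 for Rag2, -1.87 for Pax5, -1.98 for Hcls1, -2.97 for Robo2, -8.70 for Rab7b and -2.08 for Nid2. It was 10.66 for Hr, 9.08 for Ddit4l, 6.89 for Vasn, 5.79 for F2r, 4.41 for Nlgn2 and 4.95 for Cdkn1a. Limma voom called none of these 6 (adjusted p = 0.123, 0.0881, 0.164, 0.240, 0.318 and 0.187), and Nlgn2 was not called either with the compared groups alone (0.254) or without sh-Eif5a replicate 1 (0.199). The values of Hr, Ddit4l and Vasn are fitted against 0, 1 and 3 reads in sh-Eif5a and are no bounds: by counts Hr was at least 119-fold higher, Ddit4l 688-fold (95% exact counting interval 123 to 27202) and Vasn 121-fold (41.1 to 589). Reads outside transcripts, which no comparison uses, made up 18.3 and 24.7% in the sh-Eif5a libraries and 36.0 and 21.3% in sh-Dhps, above the 15.5 and 17.5% of sh-Ren.

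Of 27 tested B-lineage, pro-B and pre-B markers 24 had a mean under 1 CPM in sh-Ren, and Sox4 (78.5 CPM), Bach2 (2.27) and Erg (1.76) did not. Reads lost to other isoforms are argued against by the 23 of 27 members with 1 transcript, whose median log2 ratio of sh-Eif5a over sh-Ren was 11.46. An exchange of sh-Ren with the sh-Dhps or sh-Eif5a libraries is argued against by Dhps and Eif5a, which were 6.01 and 41.6 times as high in sh-Ren as in the libraries named after them (ratio of mean CPM). The sh-Ren cultures may have held cells other than leukocytes: 17 genes of leukocytes in general, those of a list of 25 with at least 20 CPM in sh-Eif5a (2 stand in another list), had a median ratio of 0.00118, with Coro1a at 1.49 against 584 CPM and Cd53 at 0.141 against 527. The same 17 genes argue against the depletions alone as the reason for the low values in sh-Ren. Their median was 0.141 CPM there, in libraries labelled as the same lymphoma without either depletion. It was 160 CPM in sh-Eif5a and 62.6 in sh-Dhps. Whether the depletions added to these differences was not tested.

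The sh-Dhps libraries lay between the other groups for most of these genes. A single mixture of both kinds of cells without other changes would give 1 ratio of sh-Dhps to sh-Eif5a. This was examined over 90 protein-coding genes with at least 50 CPM in sh-Eif5a and at most 1 in sh-Ren. The deviations from that ratio in both sh-Dhps libraries, each taken over another sh-Eif5a library, correlated at r = 0.872 (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). Genes are not independent. Of these genes 16 lay over 2-fold from the median on the same side in both, which argues against 1 ratio. What made the ratios differ by gene, such as either depletion, was not tested, and a mixture together with other changes stays open.

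The neighbours Atad1 and Pten were near 0 in sh-Dhps and sh-Ren. Reads lost to isoforms are argued against, since both have 1 transcript and at least 80.3 CPM in sh-Eif5a. Depletion of Dhps as the cause in sh-Dhps stays open: in sh-Ren, without that depletion, the median ratio to sh-Eif5a was 0.000347, but sh-Ren is no control for it if its cells were of another kind. A segment of chromosome 19 may be missing in the cells. Among protein-coding genes with at least 20 CPM in sh-Eif5a, 16 were at least 32-fold lower in sh-Dhps. They held 1 pair of neighbours, where random genes averaged 0.0226 (one-sided permutation p = 0.0223, 10000 permutations). That pair prompted the test, so its p only describes it.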

How the results depend on the processing

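Most alternatives were chosen before the data were examined; unsummed transcripts, single-transcript genes and leaving out genes under 1 CPM were chosen after. Among 5086 comparisons of single genes with their reported value, 4567 kept their side of the threshold, 264 lost and 255 gained a call, and no call reversed (0). Among 1520 of lists it was 1338, 70, 110 and 2. Of those that kept their side, 15 for genes and 73 for lists had the other sign, 0 of them past the threshold. The 2 are lists of sh-Dhps against sh-Ren for which camera, without a call as reported, turned its direction without sh-Dhps replicate 1: nucleotide synthesis (median 0.29) and ribosome biogenesis (0.33). Their reported medians, 0.09 and 0.01, had that sign already, and it was without sh-Dhps replicate 2 that the medians turned, to -0.28 and -0.32, with both called. With each library left out they ranged from -0.28 to 0.29 and from -0.32 to 0.33. Eif5a in sh-Eif5a passed at -5.38 with DESeq2, -5.37 without a filter and -5.62 with the replicate block, and ranged from -11.46 to -4.36 with each library left out. The value of -11.46 is fitted with sh-Eif5a replicate 1 alone in its group, which held 0 Eif5a reads, and is no bound. Genes changed in sh-Eif5a numbered 2241 with DESeq2 (857 to 2316 with each library left out). In sh-Dhps they numbered 1332 with DESeq2, 1235 without a filter, 345 with the compared groups alone and 242 without genes under 1 CPM, which tests fewer genes (651 to 1808). Between the depletions they numbered 977 and 859 with DESeq2 and without a filter (277 to 1359). Shared calls numbered 935, 852 and 172 with DESeq2, without a filter and without genes under 1 CPM (448 to 1079). Lists past the threshold in sh-Eif5a, 7 as reported, numbered 2 with an estimated correlation, 3 with fry, and 11 with limma voom and without a filter (5 to 14). In sh-Dhps, 11 as reported, they numbered 2, 3 and, without genes under 1 CPM, 7 (6 to 17). Between the depletions, 6 as reported, they numbered 0, 2 and, with limma voom, 10 (5 to 15). Where no reason is given the cause was not tested. A library left alone in its group is assumed to vary like the others. The samples share only a number, and deviations of equally numbered replicates correlated at -0.0192, 0.140 and -0.007, so the block is a check alone. The shift of proteins with proline tracts, with its alternatives, was not run. At this depth and spread 8 to 18% of planted 2-fold changes were found.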

Other observations

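The tests of this part were chosen only after the result was seen, and the genes it names were chosen after their values were seen. Of 166 tested small RNA genes 39 were lower and 0 higher than in sh-Ren by edgeR's quasi-likelihood test (median log2 fold change -3.37), and 28 lower and 1 higher than in sh-Eif5a (-2.82). Among them 87 snoRNA genes had medians of -3.81 and -3.28, with 34 and 26 lower. Over all 10846 genes 205 and 125 were lower in sh-Dhps. In sh-Eif5a against sh-Ren 2 of the 166 were lower and 4 higher. Small RNA are not messenger RNA, so their reads are no footprints of translating ribosomes and say nothing about translation. The snoRNA share of transcript reads ran from 0.102% (sh-Dhps replicate 1) to 0.646% (sh-Ren replicate 1), and what set it was not tested. No test of small RNA as a set was run. Limma voom called 18 and 13 lower in sh-Dhps. Left-out libraries change which genes are tested, and the medians. Against sh-Ren the small RNA median was -0.72 and -4.59 without sh-Ren replicate 1 or 2. It was -4.21 and -4.22 without sh-Eif5a replicate 1 or 2, and -5.84 and -4.43 without sh-Dhps replicate 1 or 2. Against sh-Eif5a it was, in the same order, -2.83, -2.08, -1.36, -1.16, -2.45 and -2.25. The snoRNA medians ranged from -4.28 to -2.33 against sh-Ren and from -3.65 to -2.41 against sh-Eif5a. In sh-Ren replicate 1 miRNA held 0.188% of transcript reads, against 0.0133% in sh-Ren replicate 2, so the size against sh-Ren depends on replicate 1. In sh-Eif5a against sh-Ren the small RNA median was -0.57 with all libraries, 0.92 without sh-Ren replicate 1 and -1.32 without sh-Ren replicate 2. It ranged from -1.56 to -1.08 without a library of another group.

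There were 92 protein-coding genes with at least 50 CPM in sh-Ren and at least 8-fold lower in sh-Eif5a. In sh-Dhps 26 of them lay within 2-fold of sh-Ren and 9 over 8-fold lower, with a median ratio of 0.372. In the order sh-Ren, sh-Eif5a and sh-Dhps, Hapln1 stood at 593, 30.7 and 59.6 CPM, Ptn at 453, 6.79 and 69.0, and Map1b at 502, 25 and 202. Nes, under 8-fold lower in sh-Eif5a and so outside the 92 genes, stood at 387, 51.6 and 102. Anxa2 stood at 715, 24.6 and 432 CPM and Csn3 at 424, 13.8 and 310, while Hspb1 stood at 208, 7.69 and 245 and Nid2, lowest in sh-Dhps, at 850, 62.9 and 14.9. Among protein-coding genes with a mean of at least 10 CPM in sh-Dhps, 6 had means there over 8-fold above both other groups. Of these Gpnmb, at 62.8 CPM against 3.45 in sh-Ren and 2.48 in sh-Eif5a, passed against both (edgeR's quasi-likelihood test, adjusted p = 0.00121 and 0.00178). Flnc also passed (0.0139 and 0.00656), but not with limma voom (adjusted p = 0.199 and 0.253) or, against sh-Ren, without sh-Dhps replicate 2 (0.240). Fcer1g passed against sh-Ren (0.0193) but not sh-Eif5a (0.218), and against sh-Ren neither with limma voom (0.0520) nor without sh-Dhps replicate 1 (0.0916). Angpt2 (0.174 and 0.0623), Cxcl10 (0.395 and 0.0899) and Mlx (0.356 and 0.425) passed neither. With a library left out, against sh-Ren these 3 passed without sh-Ren replicate 1 (0.00121, 0.000294 and 0.00240) and Angpt2 without sh-Ren replicate 2 (0.0373). Against sh-Eif5a, Angpt2, Cxcl10 and Fcer1g passed without sh-Ren replicate 1 (7.14e-05, 3.78e-05 and 0.0160) or 2 (4.76e-09, 5.13e-10 and 0.00451), Mlx without sh-Ren replicate 2 (0.0193), and Angpt2 and Cxcl10 without sh-Dhps replicate 2 (0.0424 and 0.0159). Other settings also gained calls. Against sh-Eif5a, Angpt2 and Cxcl10 passed with DESeq2 (adjusted p = 4.22e-05 and 0.000290). By edgeR they passed without a filter on low counts (0.000114 and 3.45e-05), with the compared groups alone (0.00200 and 0.00109) and with the replicate block (0.0181 and 0.0214). Fcer1g passed there with DESeq2 (0.0110) and by edgeR with the compared groups alone (0.0229). Against sh-Ren, Angpt2 passed with DESeq2 (0.0215) and by edgeR without a filter (0.0308). Beside Cdkn2a, Klhl9 stood at 209, 192 and 178 CPM, and Cdkn2b at 0, 9.74 and 0.776. Near Pten, Minpp1 stood at 48.9, 72.4 and 103 CPM and Stambpl1 at 11, 50.2 and 28.6.

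The cultures may differ in chromosome copy number. This was examined over 5342 protein-coding genes with at least 10 CPM in every group. Medians of the log2 fold change of sh-Eif5a against sh-Ren per chromosome were 0.43 on chromosome 8, 0.34 on 12, 0.24 on 14, -0.26 on 19 and -0.33 on 3. Their SD was 0.179, against a mean of 0.0541 after shuffling genes over chromosomes (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). The SD was 0.0820 against 0.0461 after shuffling in sh-Dhps against sh-Ren, and 0.126 against 0.0426 between the depletions (same permutation test, p = 0.0001 each). Genes are not independent, and neighbours regulated together would also raise these SDs.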
